A study of Mus musculus with 405 samples.

How the data were processed

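Single cells were captured on Fluidigm C1 chips, and cDNA was made with the SMARTer chemistry and turned into libraries with Nextera XT, per the labels' protocols. Spike-in RNA was added at 1 in 40000, and at 1 in 4000 in the day 5 run. The submitters' processing notes name CASAVA 1.8.2, cutadapt 1.2.1, Bowtie2 2.1.0, TopHat2 2.0.8, Cufflinks 2.0.2 and the build mm10, without saying in which order or for what. The authors deposited 1 table of log2 FPKM for 405 cells and 22524 gene columns, which include the EGFP and rtTA transgenes. The gene annotation, the filter on cells and any doublet removal are not given in the sources used here. No deposited log2 value is below 0, and 78.7% of them are 0. Within 4 classes of gene length the density of positive values below 0.1 was 0.881 to 0.972 of that between 0.1 and 1, as a floor at an FPKM of 1 gives. A value of 0 was therefore read as an FPKM of 1 or below, and linear FPKM was obtained as the power of 2. FPKM is relative to each cell's own mapped fragments and to gene length, so a few abundant RNAs lower the values of all others in a cell. Actb, Gapdh and Eef1a1 were above 0 in all 405 cells and Tbp was at 0 in 63.2% of them, so a 0 does not mean that a gene is off.

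The table also holds the authors' class of each cell, the run, the day and a Tau-EGFP score per cell. This deposited score is a log intensity, per the file headers, with no base or instrument stated, and it was 0 in all cells of the day 0 and day 2 runs. Cells were assigned to groups through the run name, which the sample titles share. Single cells could not be matched to single titles, and none was left out of the main values.

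From these values the mean, the SD over cells and the share of cells above 1 FPKM were computed per run, with 95% exact (Clopper-Pearson) intervals. A share of 0 is given with the limit that 3 cells of the total would set. Intervals and limits cover counting error only. Day 22 of Ascl1 alone is the mean of 2 runs with equal weight. The labels name no animal or culture per cell, so each run counts as 1 sample and no test, standard error or p-value was computed. The difference between the 2 day 22 runs served as the measure of run-to-run spread.

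Gene lists and the rule for named genes were fixed before the data were examined. A list difference is the median over its measured members of the difference in mean log2 FPKM. Its percentile was taken among 10000 random lists of the same size, drawn from the same of 50 bins of mean expression. A difference of 1 log2 unit as a clear size for counting members was chosen after seeing the data, as were the cuts of 1 for the microglia and 2 for the astrocyte score, the limit of 100 FPKM for muscle genes, the limit of 1.5 for opposite differences and which list differences were recomputed under the alternatives. The score of a cell is the mean log2 FPKM over a list. Named genes were Ascl1, Pou3f2, Myt1l and Mapt, and for each comparison the 10 largest differences in each direction among genes above 1 FPKM in at least 50% of the cells of the higher group. Predicted genes, small RNAs, clone names ending in Rik and mitochondrial genes were left out, a difference at day 22 had to have the same sign in both runs, and up to 4 members of a list with the largest differences served as its examples. The split of failed cells at the lowest Myocyte cell was also chosen after seeing the data. Sox4, Acta2 at day 2, Snap25 at day 5 and the Tubb3 values at day 5 and in the clonal run are further examples, chosen after their values were seen.

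The steps were tested on simulated data made by resampling the day 0 cells against themselves over 22524 genes. In 20 draws, a 20-member list raised by 2 came out at a mean of 1.89 with a percentile of 100 in every draw. One lowered by 1 came out at -0.82 with a percentile of 0.0, and an unchanged list at 0.0007 with percentiles from 1.29 to 98.0. All 10 top genes per draw were truly raised. Both sides of each draw came from the same run, so the simulation held no run-to-run difference. It therefore does not show how percentiles or named genes behave in comparisons between runs. Alternatives were the log2 ratio of mean FPKM, log2(FPKM + 10), cells rescaled to a total of 1000000, members at a mean log2 FPKM of at least 1, cells with at least 2000 genes, the mean over members, other detection limits of 5 and 10 FPKM, and leaving out each day 22 run. Others were chosen after seeing the data. Symbols of list members that the table gives under an older name were matched by an alias table made after seeing the columns. Gene positions are from GENCODE release M21, which is on the build mm10, counted from 1. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.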

Results

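Messenger RNA was sequenced from 405 single mouse cells during the conversion of embryonic fibroblasts into induced neuronal cells. Fibroblasts were taken from the tail tips of embryos of mice carrying EGFP in the Tau (Mapt) locus, and Ascl1, a proneural transcription factor, was switched on with doxycycline. The cells were captured on 8 microfluidic runs. These held 73 untreated fibroblasts (day 0), 81 virally infected cells at day 2, 47 cells at day 2 from a clonal line in which each cell carries the same Ascl1 copies, and 55 cells at day 5. The late runs held 33 cells at day 20, 34 and 39 cells in a pair of runs at day 22 (iN7 and iN8), and 43 cells at day 22 that received Brn2 (Pou3f2) and Myt1l together with Ascl1. Cells of the late runs had been replated onto glia at day 7. Per the labels, day 0 and day 2 cells were unsorted, Tau-EGFP-positive and negative cells were mixed equally at day 5, and late cells were sorted for Tau-EGFP. Values are log2 FPKM, where 0 stands for an FPKM of 1 or below. The labels name no animal or culture for a cell, so each run is 1 sample, SDs are over cells, and no difference between runs was tested.

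The number of mapped reads behind each cell is unknown. The median cell listed 5814 genes above 1 FPKM at day 0, with an SD of 632 over 73 cells. The medians were 4241 (SD 762, n = 81) in the virally infected day 2 run, 4654 (SD 564, n = 47) in the clonal run and 5164 (SD 1007, n = 55) at day 5. They were 4775 (SD 1012, n = 33) at day 20, 4026 (SD 948, n = 34) and 3332 (SD 645, n = 39) in the day 22 runs iN7 and iN8, and 5603 (SD 946, n = 43) with 3 factors. Most genes stood lower in the induced runs than at day 0. Among genes listed in at least 50% of the cells of either group, the median difference from day 0 was -0.87 at day 2, -0.73 in the clonal run, -0.71 at day 5, -0.66 at day 20, -1.39 at day 22 and -0.49 with 3 factors. Ribosomal protein genes were lower in every induced run, by a median of -1.39 at day 2 (percentile 0.080) and -2.27 with 3 factors (percentile 0.190). Percentiles place the median of a gene list among those of 10000 random lists of the same size and mean expression.

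Ascl1 (chromosome 10, 87490819 to 87493660, minus strand, build mm10) was listed at 0 in all 73 fibroblasts, which allows a share of up to 4.11%. It was above 1 FPKM in 86.4% of virally infected day 2 cells (70 of 81, 95% exact interval 76.999% to 93.0%) and in 47 of 47 clonal cells (92.5% to 100%). The mean was 5.04 ± 2.62 (SD, n = 81) in the first and 8.24 ± 1.25 (n = 47) in the second. At day 5 it was 6.29 ± 2.89 (n = 55), and at day 20 7.40 ± 2.91 (n = 33). At day 22 it was 5.41 ± 1.78 (n = 34) in iN7, 6.03 ± 2.17 (n = 39) in iN8 and 5.82 ± 3.28 (n = 43) with 3 factors. Pou3f2 (chromosome 4, 22482780 to 22488366, minus strand) was above 1 FPKM in 30 of 43 cells of the 3-factor run and in at most 3 cells of any other run. Myt1l (chromosome 12, 29528384 to 29923213, plus strand) was above 1 FPKM in 28 of those 43 cells. Mapt (chromosome 11, 104231390 to 104332090, plus strand), which encodes Tau, was listed in 1 of 73 fibroblasts, 25 of 55 day 5 cells, 24 of 33 day 20 cells, 27 of 34 cells of iN7, 23 of 39 cells of iN8 and 37 of 43 cells with 3 factors. Its mean was 0.01 ± 0.09 at day 0, 1.43 ± 1.85 at day 5, 2.22 ± 1.90 at day 20, 2.33 ± 1.71 in iN7, 1.58 ± 1.79 in iN8 and 3.74 ± 2.06 with 3 factors.

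**Figure D1:**
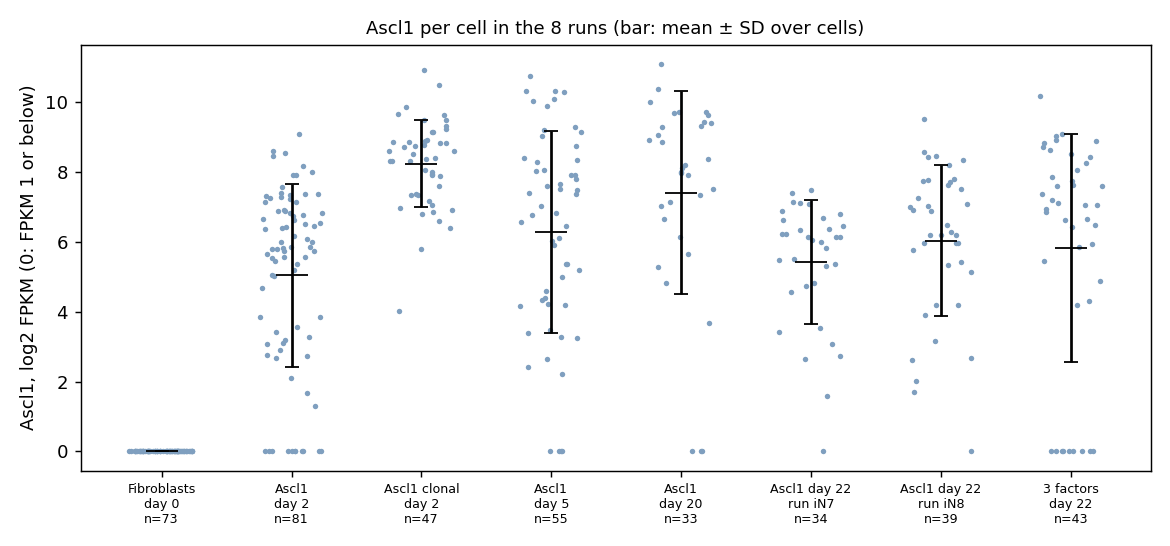
Ascl1 in log2 FPKM for each cell (point) of the 8 runs, with the mean and SD over cells as a bar and the number of cells under each run. All 73 day 0 cells sit at 0, and the clonal day 2 cells have a mean of 8.24 against 5.04 in the virally infected cells.

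The first comparison asked how fibroblasts respond in the first days of Ascl1. At day 2, Snca (alpha-synuclein) was higher than at day 0 by 5.51, Prune2 by 5.10, the Notch-related proneural gene Hes6 by 4.60, the cell cycle inhibitor Cdkn1c by 4.49 and the Notch ligand Dner by 3.88. Cardiac troponin T, Tnnt2, was higher by 3.97. Within the day 2 run it was 6.16 ± 3.36 in the authors' induced class (n = 51) and 0.13 ± 0.22 in their MEF class (n = 10). Tnnc1 was 5.64 ± 4.04 and 0 in these classes, which were made from the same cells. The skeletal muscle score was 0.62 ± 0.48 at day 2 (n = 81), 0.74 ± 0.44 in the clonal run (n = 47) and 0.46 ± 0.41 at day 5 (n = 55). At day 0 it was 0.13 ± 0.09 (n = 73). Lrrc17 and the imprinted gene Mest were higher by 4.66 and 3.78, and the rtTA transgene by 5.27. Il1rl1 and Plaur, the urokinase receptor gene, differed by -5.18 and -5.03 and Anxa3 by -5.19. Among the 10 named genes with the largest negative differences were Tm4sf1 at -5.94, Tagln2 at -5.85, the caveolar protein gene Cav1 at -5.57, the protease inhibitor gene Timp1 at -5.49 and S100a4 at -5.12. Hes6 had a mean of 0.70 ± 1.49 (SD, n = 73) at day 0 and 5.31 ± 2.75 (n = 81) at day 2. Cav1 had 9.45 ± 0.64 and 3.88 ± 4.30 in the same cells. By the rule for named genes, the 10 largest differences between the 2 day 22 runs were 3.86 to 5.32 in one direction and -3.85 to -4.76 in the other. Of the genes named as higher at day 2, only Snca was beyond that range. The others cannot be told apart by size from run-to-run spread. Within the day 2 run, Hes6 was 6.82 ± 1.47 in the authors' induced class (n = 51) and 0.08 ± 0.21 in their MEF class (n = 10).

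Cell cycle genes stood far below the fibroblast level at day 2. All 23 measured G2/M genes were lower by at least 1, with a median of -2.30 and a percentile of 0.0, and 18 of 19 G1/S genes were lower by at least 1, with a median of -2.41 and a percentile of 0.0. Rrm2, a subunit of ribonucleotide reductase, differed by -5.31. Among 32 fibroblast matrix genes 18 were lower by at least 1, none was higher by as much, and the median was -1.16 (percentile 0.170). Of 14 actin and contractile genes 12 were lower by at least 1, with a median of -2.28 (percentile 0.010), and Acta2 (smooth muscle actin) had a mean of 10.49 ± 1.64 at day 0 and 7.17 ± 3.55 at day 2. Among 24 proneural targets 5 were higher by at least 1 and 1 was lower, led by Hes6, Zfp238 and Sox11, and the list's median of 0.07 stood at percentile 100. Among 22 pan-neuronal genes the median difference at day 2 was 0 (percentile 97.4). The size of these medians depended on the scale: the fibroblast matrix median was -0.51 with log2(FPKM + 10) and -0.28 relative to the median gene, the G2/M median -0.97 and -1.42, and the G1/S median -0.98 and -1.53. The proneural median was 0.94 relative to the median gene, 0.65 as a mean over members, 0.36 with the log2 ratio of mean FPKM and 1.1 with members at a mean log2 FPKM of 1 or more.

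At day 5, neuronal genes stood above the fibroblast level. Of 22 pan-neuronal genes 13 were higher by at least 1 and none was lower by as much, with a median of 1.26 at percentile 100. Tubb3, the neuronal beta-tubulin, had a mean of 0.90 ± 1.90 (n = 73) at day 0 and 5.04 ± 3.52 (n = 55) at day 5. The synaptic vesicle fusion protein gene Snap25 was listed at 0 in every day 0 cell and had a mean of 2.87 ± 3.19 at day 5. Other large differences were those of Ascl1 (6.29), D0H4S114 (5.58), the angiotensin receptor gene Agtr2 (5.47), Ifi27l2a (5.42), Dner (5.22) and Itm2a (4.25). Those of Dner and Itm2a lay within the 3.86 to 5.32 of the largest differences between the 2 day 22 runs. The largest negative differences were those of Timp1 (-8.34), Anxa3 (-7.73), Arhgdib (-7.52), Rrm2 (-7.48), Il1rl1 (-7.18), Tm4sf1 (-7.13) and Acta2 (-7.05). With log2(FPKM + 10) the pan-neuronal median was 0.46, and with members at a mean log2 FPKM of 1 or more it was 2.28. Interferon-stimulated genes were higher, 9 of 12 by at least 1, with a median of 1.89 at percentile 100 that was 0.71 with log2(FPKM + 10) and 3.46 with the log2 ratio of mean FPKM. Of 13 early response genes 5 were higher by at least 1, led by Fos and Egr1, with a median of 0.85 (percentile 99.99). The fibroblast matrix list was mixed, with 17 of 32 genes lower and 5 higher by at least 1 and a median of -1.05 (percentile 0.780) that was -0.34 relative to the median gene and -0.22 with the log2 ratio of mean FPKM. The day 5 run differed from the others in its spike-in dilution, 1 in 4000 against 1 in 40000.

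At days 20 and 22, the RNAs that stood highest above day 0 were mostly those of skeletal muscle. At day 20 the fast myosin light chain gene Myl1 was higher by 11.60, the troponin genes Tnni1 and Tnnc2 by 11.50 and 11.06, and skeletal actin Acta1 by 11.30. Mylpf, Tnnt3, the muscle phosphoglycerate mutase Pgam2, Tnnt2 and Cox8b were higher by 10.17, 10.02, 9.68, 9.22 and 8.35. At day 22, as the mean of 2 runs, Myl1 was higher by 9.41, Tnni1 by 9.35, Tnnc2 by 9.43 and Acta1 by 8.98. Of 32 skeletal muscle genes 21 were higher by at least 1 at day 20 (median 2.74) and 20 at day 22 (median 1.34), none was lower by as much at either time, and both medians stood at percentile 100. The day 22 median was 1.88 in run iN7 and 0.99 in run iN8, and the medians at days 20 and 22 were 1.58 and 0.69 with log2(FPKM + 10), 5.81 and 5.4 with the log2 ratio of mean FPKM, and 9.22 and 7.29 with members at a mean log2 FPKM of 1 or more. Of 22 pan-neuronal genes 4 were higher by at least 1 at day 20 (median 0.02, percentile 77.5) and 2 at day 22 (median 0.16, percentile 99.9). The size at day 22 depended on the scale, at 1.56 relative to the median gene, 1.06 with the log2 ratio of mean FPKM and 0.85 with members at a mean log2 FPKM of 1 or more. Fibroblast matrix genes were lower, 25 of 32 by at least 1 at day 20 (median -2.33) and 28 of 32 at day 22 (median -3.15), both at percentile 0.0. S100a6 differed by -10.67 and Acta2 by -9.64 at day 22, and all 23 G2/M genes were lower by at least 1 at both times. Early response genes stood above day 0, 7 of 13 by at least 1 at day 20 (median 1.40, percentile 100) and 5 at day 22 (median 0.51, percentile 99.98), led by Atf3 and Fos. The day 20 median was 0.68 with log2(FPKM + 10). The astrocyte list had a median of 0.78 at day 20 and 0.35 at day 22, both at percentile 100, with 6 of 13 genes higher by at least 1 at day 20. Its genes were also listed before glia were present, as the score was 0.75 ± 0.24 (n = 73) at day 0 and 0.70 ± 0.57 (n = 55) at day 5 against 1.59 ± 1.61 (n = 33) at day 20, 0.63 ± 0.69 (n = 34) in iN7 and 1.01 ± 1.14 (n = 39) in iN8. The median of the microglia and macrophage list was 0 at day 20 (percentile 39.7) and 0.29 at day 22 (percentile 100), and its score was above 1 in 1 cell of iN7 and 5 cells of iN8.

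**Figure D2:**
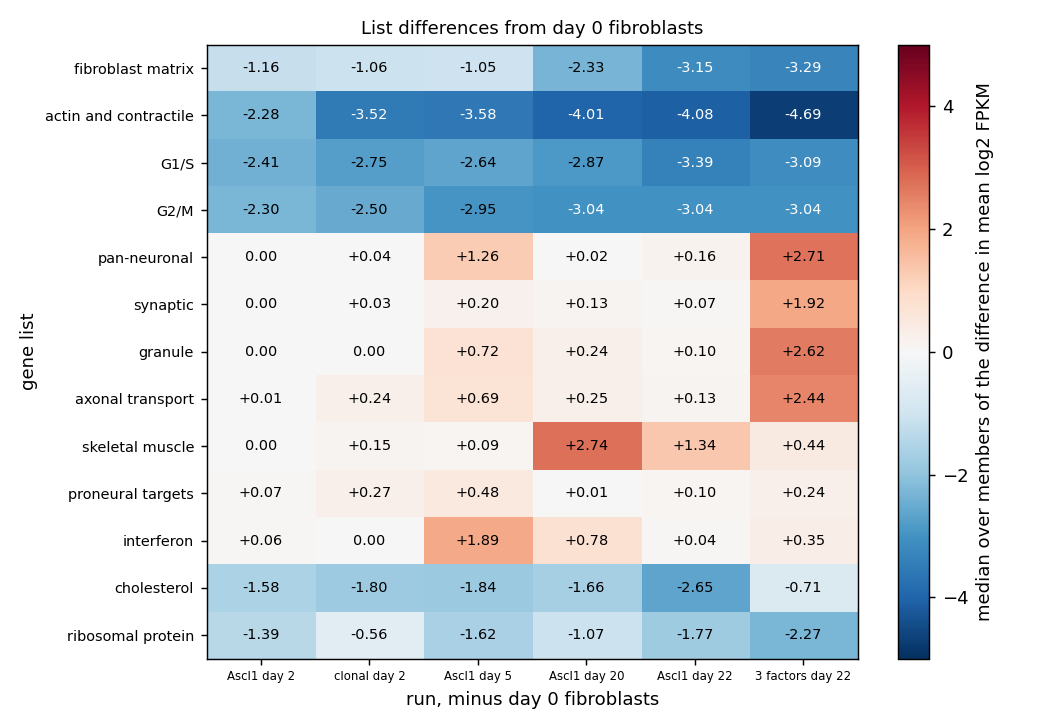
Median over the members of 13 gene lists of the difference in mean log2 FPKM between each induced run (columns) and the day 0 fibroblasts, printed in each cell and shown as colour. Fibroblast, contractile and cell cycle lists were negative throughout, skeletal muscle reached 2.74 at day 20, and the pan-neuronal list reached 2.71 with 3 factors.

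The clonal line addressed whether uniform transgene copies give a uniform response. Ascl1 was higher in clonal than in virally infected day 2 cells by 3.20, and its SD over cells was lower, 1.25 against 2.62. Within the cells the authors class as induced at day 2, the SDs differed by only -0.06 and the means by 1.72. That restriction was chosen after seeing the data, and all 47 clonal cells against 51 of 81 infected cells (62.96%, 51.5% to 73.4%) are in that class. Over all cells, the SD of the proneural target score was 0.42 in the clonal and 0.50 in the infected run. In the same order it was 1.11 and 1.14 for fibroblast matrix and 0.44 and 0.48 for muscle genes. For pan-neuronal genes it was 0.31 and 0.27, and for G2/M genes 1.89 and 1.51. The narrower spread of Ascl1 thus did not go with a narrower spread of every score. Of 24 proneural targets 6 were higher by at least 1 in the clonal run and none was lower by as much. The list's median of 0.24 stood at percentile 99.99, beside a median difference of 0.21 over genes listed in at least 50% of the cells of either run. Sox4 had a mean of 3.03 ± 1.47 (n = 47) against 1.47 ± 1.36 (n = 81). Tubb3 had a mean of 6.63 ± 3.06 against 3.83 ± 2.75. The extracellular genes Mfap4, Ptn and Igfbp5 were higher by 5.17, 4.72 and 3.89. Grb10 differed by -4.87, S100a6 by -4.15, S100a4 by -3.94 and Cav1 by -3.88. Atp6v0c was higher by 6.53, Erdr1 by 6.07, and the respiratory chain genes Ndufs5 and Ndufb7 by 5.62 and 4.19. Reads of Atp6v0c are hard to tell from those of a processed copy with 99.8% of its bases, so that value is uncertain, and Atp6v0c and Ndufs5 also differed by -3.87 and -3.85 between the 2 day 22 runs (iN7 minus iN8). By the same rule, the 10 largest differences between those 2 runs were 3.86 to 5.32 in one direction and -3.85 to -4.76 in the other. Differences of that size between the 2 day 2 runs cannot be told apart from run-to-run spread.

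Cells that received 3 factors had higher neuronal and lower contractile RNAs than day 0 fibroblasts. Snca was higher by 6.61, Tubb3 by 6.55, Snap25 by 5.98, Bex2 by 5.80, Rtn1 by 5.79, Syt4 by 5.71 and Snhg11 by 5.55. S100a6 differed by -10.38, Acta2 by -9.56, Tagln by -9.36, Cav1 by -9.04 and Anxa1 by -8.66. Of 22 pan-neuronal genes 20 were higher by at least 1 (median 2.71), as were 18 of 27 synaptic genes (1.92), 8 of 10 granule genes (2.62) and 10 of 12 axonal transport genes (2.44), all at percentile 100. All 14 actin and contractile genes and 27 of 32 fibroblast matrix genes were lower by at least 1, with medians of -4.69 and -3.29, both at percentile 0.0. Of 8 repressors of neuronal genes 5 were lower by at least 1, led by Id3 and Id1 (median -1.17, percentile 3.56). The skeletal muscle median was 0.44 (percentile 99.99), with 5 of 32 genes higher by at least 1.

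The comparison of 3 factors with Ascl1 alone at day 22 showed neuronal RNAs in one and muscle RNAs in the other. With 3 factors Stmn2 was higher by 6.12, Syt4 by 5.86, Zcchc12 by 5.79, the growth cone gene Gap43 by 5.70, Tubb3 by 5.52 and Snap25 by 5.36. Acta1 differed by -9.06, Tnnt2 by -8.27, Tnni1 by -7.99 and Tnnc2 by -7.74. Of 22 pan-neuronal genes 20 were higher by at least 1 (median 2.57), as were 17 of 27 synaptic genes (median 1.63), 8 of 10 granule genes (2.66), 10 of 12 axonal transport genes (2.61) and 10 of 22 ion channel genes (0.83). All 5 medians stood at percentile 100, while the median gene listed in at least 50% of the cells of either side was itself higher by 0.95. Relative to that gene the pan-neuronal median was 1.62, the synaptic 0.68 and the granule 1.71, and with log2(FPKM + 10) they were 1.16, 0.59 and 1.51. Of 15 cholesterol synthesis genes 10 were higher by at least 1, with a median of 1.54 (percentile 99.95) that was 0.59 relative to the median gene, 0.63 with log2(FPKM + 10) and 0.13 between Myocyte-class cells. Early response genes were lower than with Ascl1 alone, 7 of 13 by at least 1, with a median of -1.02 (percentile 0.0), and had a score of 1.60 ± 1.02 (n = 43) against 1.67 ± 0.63 (n = 73) at day 0, 2.90 ± 1.13 (n = 34) in iN7 and 2.40 ± 1.02 (n = 39) in iN8. Of 32 skeletal muscle genes 16 were lower by at least 1, with a median of -1.02 (percentile 0.0) that was -0.61 against iN8 alone and -1.52 against iN7 alone. The 2 Ascl1 runs differed from each other by up to 2.64 in 95% of the genes listed in at least 50% of the cells of either run. Between the Myocyte-class cells of both sides the pan-neuronal difference was -0.12 and the muscle difference 0.71, both of the opposite sign, with the synaptic and granule medians at -0.04 and -0.10, in 6 cells with 3 factors.

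The authors' classes, which were made from these same cells, divide the runs differently. With 3 factors 32 of 43 cells were Neuron (74.4%, 58.8% to 86.5%), 6 Myocyte and 5 Fibroblast. With Ascl1 alone none of 106 late cells was Neuron, which allows a share of up to 2.83%, while 66 of 73 day 22 cells were Myocyte (90.4%, 81.2% to 96.1%) and 17 of 33 day 20 cells (51.5%, 33.5% to 69.2%). At day 20, 12 cells were in the failed class, and 22 of 33 cells had a Tau-EGFP intensity above 0. At day 5, 16 of 55 cells were early induced neurons, 24 intermediate, 13 failed and 2 early myocytes. The intervals cover counting error only. Neuron cells with 3 factors had a pan-neuronal score (mean log2 FPKM of the list) of 4.78 ± 0.87 (n = 32) against 0.85 ± 0.27 (n = 6) in Myocyte cells of the run. Their muscle scores were 0.10 ± 0.10 and 4.07 ± 1.96. At day 5, early induced neurons had an interferon score of 0.46 ± 0.53 (n = 16) against 3.50 ± 1.15 (n = 13) in the failed class, and a fibroblast matrix score of 0.86 ± 0.57 against 5.29 ± 0.66. Myocyte minus Fibroblast cells could be taken in 2 runs, with at least 3 cells of each class. The fibroblast matrix score differed by -3.84 at day 20 and -4.83 with 3 factors, and the muscle score by 0.59 and 3.94, so its mean of 2.27 rests on the 3-factor run.

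**Figure D3:**
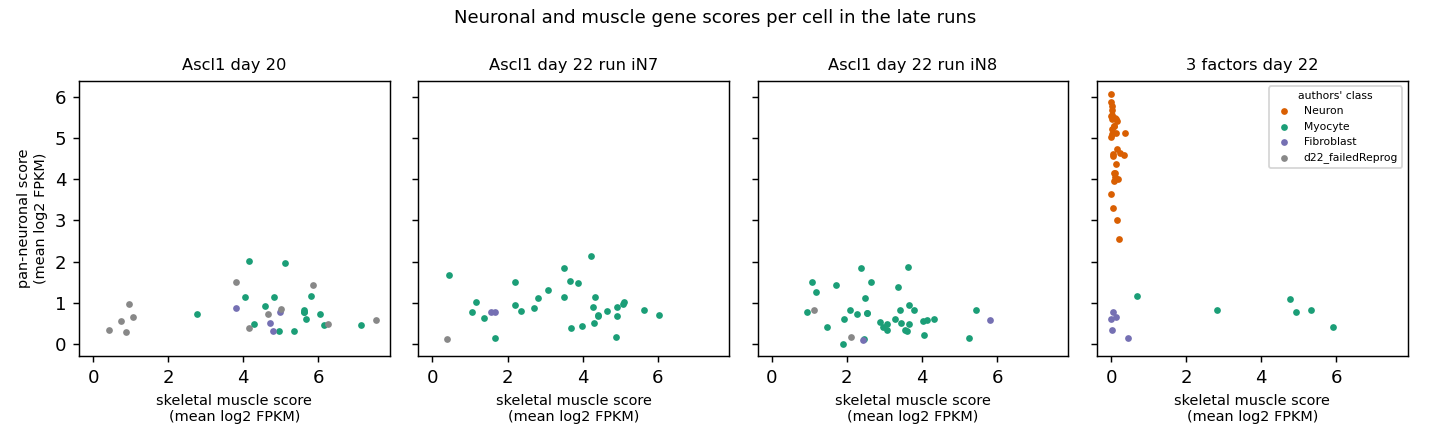
Pan-neuronal score against skeletal muscle score, both as mean log2 FPKM over the list, for each cell of the 4 late runs, coloured by the authors' class. Neuron cells of the 3-factor run average 4.78 on the neuronal score and 0.10 on the muscle score, and no cell of the Ascl1 runs is of that class.

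Relations of Ascl1 to list scores were taken across the cells of each run, and their differences between runs were not tested. In 81 virally infected day 2 cells Pearson's r of Ascl1 with the proneural target score was 0.81 (Spearman's rho 0.74), and 0.79 without the 2 cells farthest from the median of Ascl1. With the fibroblast matrix score r was -0.70 (rho -0.70), with the G2/M score -0.61 (rho -0.68) and with the muscle score 0.64 (rho 0.65), while with the pan-neuronal score it was 0.10 (rho 0.13). Only 70 of these 81 cells listed Ascl1 and 10 were of the authors' MEF class. These r thus include the contrast of cells with and without listed Ascl1, which leaving out 2 cells does not remove. All 47 clonal cells listed Ascl1, with an SD of 1.25 against 2.62, so r is not directly comparable between the 2 runs. In 47 clonal cells r with the proneural targets was 0.43 (rho 0.28) and 0.26 without the 2 farthest cells, and with the pan-neuronal score it was 0.55 (rho 0.57) and 0.57 without them. With the fibroblast matrix, G2/M and muscle scores it was -0.13, -0.22 and 0.29 in those cells (rho -0.13, -0.29 and 0.25), and -0.12, -0.08 and 0.22 without the 2 farthest. At day 5 r was 0.88 with the proneural targets (rho 0.90, n = 55), 0.48 with the pan-neuronal score (rho 0.47), -0.45 with the fibroblast matrix score (rho -0.38), 0.39 with the muscle score (rho 0.57) and -0.04 with the G2/M score (rho -0.14). In the late runs r with the proneural targets was 0.66 at day 20 (rho 0.65, n = 33), 0.49 in iN7 (rho 0.35, n = 34), 0.51 in iN8 (rho 0.55, n = 39) and 0.75 with 3 factors (rho 0.59, n = 43), and 0.59, 0.32, 0.50 and 0.71 without the 2 farthest cells. With the muscle score it was 0.55 at day 20 (rho 0.16) and 0.31 without the 2 farthest cells, 0.40 in iN7 (rho 0.33), -0.12 in iN8 (rho -0.07), where it was 0.14 without the 2 farthest cells, and 0.23 with 3 factors (rho 0.25). Ascl1 was listed in 51 of 55 day 5 cells, 30 of 33 day 20 cells and 34 of 43 cells with 3 factors. At day 5 it averaged 2.31 ± 1.73 in the failed class (n = 13) and 7.95 ± 1.76 in early induced neurons (n = 16). The r of Ascl1 in these runs thus also include contrasts between classes or between cells with and without listed Ascl1. In day 5 cells with Tau-EGFP intensity above 0, r of intensity with the pan-neuronal score was 0.43 (rho 0.44, n = 40), and with 3 factors it was 0.59 (rho 0.59, n = 43). At day 20 it was 0.15 (rho 0.04, n = 22), in iN7 0.22 (rho -0.01, n = 33) and in iN8 0.20 (rho 0.18, n = 38). Without the 2 cells farthest from the median intensity it was 0.45 at day 5, 0.48 with 3 factors, 0.06 at day 20, -0.03 in iN7 and -0.08 in iN8. In all, 35 relations of Ascl1 and 30 of intensity were computed (over cells above 0 and over all cells), cells of a run are not independent replicates, and no p-value was computed.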

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

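The tests of Atp6v0c below were chosen after the values per run had been seen. Compared with day 0, 4 genes differed in opposite directions, each by at least 1.5, in the virally infected and the clonal cells of day 2. The gap between the lines was 6.53 for Atp6v0c, 6.07 for Erdr1, 5.62 for Ndufs5 and 4.19 for Ndufb7. With 1 run per line this difference was not tested.

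Atp6v0c and its processed copy Atp6v0c-ps2 took opposite levels in some of the runs. In mean FPKM on a log2 scale, the gene stood at 0.72 and the copy at 7.32 in the virally infected run, and at 7.70 and 6.32 in the clonal run, while both were high with 3 factors, at 7.96 and 8.43. The days and factors of the design are argued against as the only cause, since the 2 runs of day 22 differed in Atp6v0c by 3.87 in mean log2 FPKM, above the 95th percentile of 2.64 over genes. As the values had been seen, this outcome was not open when the test was chosen. It does not show whether line or day also contributed to the levels at day 2. The copy (chromosome 6, 37806086 to 37806550) shares 464 of its 465 bases with the gene's RNA, so reads assigned differently between runs are a candidate explanation. The range of the summed FPKM over the runs was 58.7% of the narrower of the 2 ranges, between the bounds of 50% and 100% for and against it. FPKM is also divided by gene length, for which the sum was not corrected. Reads moved between gene and copy could thus change the sum. A different assignment of reads therefore cannot be told apart from a difference in the true level.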

How the results depend on the processing

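No paired analysis was possible because the numbers that the runs share only name cells. The settings that centre on the median gene, leave out classes or marked cells, or keep 1 class were chosen after seeing the data. Of 40 results, 36 kept their sign under every alternative run, and 220 of 224 alternatives did not reverse a value. These totals include the genes listed per cell and the shares of cells, which cannot be negative, so their sign could not change. A value counts as moved when it changed by more than the spread between the 2 day 22 runs, or left its binomial interval. This spread is an SD pooled over lists or relations, at 0.139 for list differences and 0.215 for r. Single lists could differ more, such as muscle at 1.88 in iN7 and 0.99 in iN8. Of the alternatives of headline results 74 moved, 52 did not and 3 reversed. Of those of the other results 65 moved, 29 did not and 1 reversed. The restriction to Neuron cells on both sides could not be run, as no Ascl1 cell is of that class. Depth is unknown, so what it limits could not be measured. Except where fewer cells or members enter, the cause was not tested.

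The list medians from day 0 were -1.16 for fibroblast matrix and -2.30 for G2/M at day 2, 1.26 for pan-neuronal genes at day 5, 2.74 for muscle at day 20, and 1.34 for muscle and -3.15 for fibroblast matrix at day 22. In that order they were -0.59, -1.84, 2.67, 5.81, 5.4 and -2.32 with the log2 ratio of mean FPKM plus 1, and -0.51, -0.97, 0.46, 1.58, 0.69 and -1.53 with log2(FPKM + 10). Relative to the median gene they were -0.28, -1.42, 1.97, 3.4, 2.74 and -1.75. With cells rescaled to 1000000 the 5 from G2/M on were -2.92, 2.00, 3.24, 1.76 and -3.94, and with members at a mean log2 FPKM of 1 or more, which leaves fewer members, -4.14, 2.28, 9.22, 7.29 and -3.84. As a mean over members, fibroblast matrix was -1.63 at day 2 and -3.79 at day 22, and muscle was 4.33 and 3.03. Without either day 22 run, muscle ranged from 0.99 to 1.88 and fibroblast matrix from -3.46 to -3.

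For 3 factors minus Ascl1 at day 22, the medians were 2.57 for pan-neuronal, 1.63 for synaptic and -1.02 for muscle genes. They were 3.01, 2.38 and -1.59 with the log2 ratio of mean FPKM plus 1, 1.16, 0.59 and -0.52 with log2(FPKM + 10), 1.62, 0.68 and -1.97 relative to the median gene, and 3.55, 2.52 and -1.35 with cells rescaled. With members at a mean log2 FPKM of 1 or more, synaptic genes were at 3.48 and muscle genes at -5.71. Without either day 22 run, synaptic genes ranged from 1.54 to 1.92 and muscle genes from -1.52 to -0.61. Neuron-class cells against all Ascl1 cells gave 3.57, 2.25 and -1.30. Myocyte-class cells of both sides reversed 4 results, at -0.12, -0.04 and 0.71, and at -0.10 for granule genes, with 6 cells on the 3-factor side.

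For clonal minus infected cells, Ascl1 differed by 3.20 in mean and -1.37 in SD. These were 2.47 and -0.44 with log2(FPKM + 10), 2.41 and -0.56 in cells with Ascl1 at 1 FPKM or more, and 1.72 and -0.06 in cells of the induced class, and the SD differed by -1.91 with cells rescaled. The proneural score differed by 0.51, by 0.26 with log2(FPKM + 10) and by 0.23 in the induced class. The share of infected cells with Ascl1 was 86.4%, and 72.8% at 10 FPKM or more. For Myocyte minus Fibroblast cells the muscle and fibroblast scores differed by 2.27 and -4.33. They differed by 2.52 and -5.47 with cells rescaled, 1.54 and -2.43 with log2(FPKM + 10), 3.94 and -4.83 without day 20, and 0.59 and -3.84 without the 3-factor run.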

Other observations

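The tests of carried-over RNA, of its even spread, of cells captured together, of Ascl1 in Myocyte cells and of the regulators in Myocyte cells were chosen after the results had been seen in whole or in part. Some cells of the late runs carried RNAs of other cell types. At day 20 the astrocyte score was above 2 in 7 of 33 cells, against 1 of 34 in iN7, 3 of 39 in iN8, 0 of 43 with 3 factors and 2 of 55 at day 5, before glia were present. The microglial gene Tyrobp was listed in 26 of 39 cells of iN8 (66.7%, 49.8% to 80.9%) and in 1 of 34 cells of iN7. The highest microglia and macrophage score was 8.67, in a cell of iN7 in the failed class in which Ascl1, rtTA and EGFP were listed at 0. The 5 Fibroblast cells of the 3-factor run also had Ascl1, rtTA and EGFP at 0, while their mean Tau-EGFP log intensity was 7.39 ± 1.29 (SD, n = 5). Ascl1 at 0 was not limited to them, as some Neuron cells of that run, with pan-neuronal scores from 3.01 to 5.29, had it too.

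Muscle RNAs were not limited to the Myocyte class at day 20, where a Tau-EGFP intensity above 0 was recorded for 17 of 17 Myocyte, 4 of 4 Fibroblast and 1 of 12 failed cells, while 7 of the 12 listed EGFP RNA. Over 15 muscle genes with a mean of at least 100 FPKM in Myocyte cells, the mean log2 FPKM was 9.45 ± 1.56 (SD, n = 17) in Myocyte cells, 8.59 ± 0.59 (n = 4) in Fibroblast cells, 9.30 ± 1.60 in the 7 of 12 failed cells at or above the lowest Myocyte cell (5.41), and 1.71 ± 0.54 in the other 5. An even spread of free RNA is argued against, because failed cells differed among themselves by 10.62, from 0.85 to 11.47. An uneven carry-over would keep 1 ratio to Myocyte cells. In log2, this ratio had an SD over genes of 0.77 in failed cells and 1.04 in the 4 Fibroblast cells. Its lowest gene stood at -2.91 in failed and -4.07 in Fibroblast cells, and its median was 0.34 higher in Fibroblast cells. An uneven carry-over therefore cannot be told apart from cells that make these RNAs. The mean of the 7 failed cells differed from that of Myocyte cells by -0.15 and that of the other 5 by -7.74. As the 7 were picked for their high muscle values, this decides neither way. A myocyte and a fibroblast captured together remain a candidate explanation for the Fibroblast cells. Of these, 3 of 4 listed more genes than the 90th percentile of Myocyte cells (5350). The median day 0 fibroblast listed 5814 genes (SD 632, n = 73), in another run. A single fibroblast could thus pass this bound, so the count cannot tell a joint capture from 1 cell.

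The muscle programme itself may come from the starting culture. The skeletal muscle score was 0.13 ± 0.09 at day 0 (n = 73), with 0.415 in the highest cell. It was 0.62 ± 0.48 in infected day 2 cells (n = 81) and 4.47 ± 1.83 at day 20 (n = 33). No day 0 cell thus came near the day 20 mean, though 73 cells could miss a share of up to 4.11%. Of an origin in the starting culture, 2 forms were tested. Muscle cells that never took up the transgenes are argued against for the Myocyte class, since Ascl1 was above 1 FPKM in 89 of 89 Myocyte cells (100%). Its mean there was higher than in the other cells of each of the 4 runs. The Fibroblast class of iN8, however, held a cell with Ascl1 at 0 and a muscle score of 5.81. For cells outside the Myocyte class this form therefore stays open. Muscle regulators already on in the fibroblasts stay open: Myod1, Myf5 and Myog were each listed in 0 of 73 day 0 cells (0.0%), but of 89 Myocyte cells only 14 listed Myod1, 1 Myog and 0 Myf5. The bounds set for this test left out that such genes are often listed at 0 in cells of the programme itself, so it cannot be told apart from a response of fibroblasts to Ascl1, which stays a hypothesis.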
